A study of Homo sapiens with 46 samples.

How the data were processed

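RNA was sequenced from human cell lines. The HCT116 libraries were made from poly-A enriched RNA and the HEK293 libraries from ribosome-depleted RNA, both with TruSeq chemistry and from RNA with an integrity number above 9, per the labels' protocols. The HEK293 libraries were read on an Element AVITI instrument, per the labels' protocols. The authors deposited 1 table of estimated counts per gene and 1 table of TPM per gene for the 40 HCT116 libraries, and the same pair of tables for the 6 HEK293 libraries. Salmon 1.10.2, kallisto 0.50.0, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without saying which tool made which table. The annotation, the strand setting and the treatment of multi-mapped reads are not given in the sources used here. The estimated counts deposited by the authors were treated as not normalized, and the deposited TPM values are scaled to transcript length and library total by the authors, with sums of 948234 to 958327 in the HEK293 table. All per-sample columns were matched to 1 sample by their names, and 0 columns were left unmatched.

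The HCT116 table holds 61228 genes, all matched by name or identifier to the reference gene names, of which 20357 carry only an Ensembl identifier. The HEK293 table holds 30160 genes, of which 30021 matched. Counts were rounded to whole numbers, and totals ran from 9.53 to 45.7 M (mega) in HCT116 and from 19.6 to 28.5 M in HEK293. Genes at 0 counts were set to a floor of 3 counts over the group, and intervals on single counts are exact Poisson intervals at 95%. Reads carried no molecular identifiers, so intervals and floors cover counting error only. Genes with near-identical copies, such as the IFNL2 and IFNL3 pair, and antisense genes are uncertain, because the counting could split or mix their reads.

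Groups came from the labels. Clones 1, 7 and 9 carried the Ku80 degron, clones 1, 13 and 15 the degron without MAVS, and clones Sa11, SB and TI the doxycycline-dependent Ku70. The same clone was used in both arms of each of these comparisons, so the clone pairs the libraries. Correlations of same-clone deviations from the group means were 0.219 at 1 day, 0.0786 to 0.2 at 2 days, 0.0317 to 0.101 at 4 days and 0.0458 to 0.0637 at 6 days of IAA. With the inhibitor they were 0.3 at 2 days and 0.0189 to 0.156 at 4 days, for the inhibitor alone 0.0593 to 0.132, in MAVS-knockout clones 0.0759 to 0.349 and in HEK293 0.245 to 0.467. For 6 against 2 days of IAA they were -0.012 to 0.0611. The labels do not say that the numbered replicates of the Ku86flox/- cells were separate cultures, so p-values there measure the spread between libraries, which may be technical. Replicate libraries of every group differed by more than sampling noise in a chi-square test over genes with at least 20 summed counts.

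Differential expression was tested in R 4.3.3 with edgeR 4.0.16: TMM factors, filterByExpr by group, quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Separate fits were made for the 32 degron libraries (12 groups, 18877 genes, 20 residual degrees of freedom, biological coefficient of variation 21.7%), the 8 Ku86flox/- libraries (4 groups, 16726 genes, 4 degrees of freedom, 4.63%) and the 6 HEK293 libraries (15549 genes, 4 degrees of freedom, 20.8%). Each fit shares 1 estimate of spread over its groups. Normalization factors lay between 0.904 and 1.1, 0.974 and 1.02, and 0.925 and 1.08 in these fits. Log2 fold changes are given ± their standard error, the absolute change divided by the square root of the quasi-F statistic, and levels as CPM with a mean ± SD over libraries. Adjusted p-values are those of edgeR unless another tool is named. A difference between responses was tested as a contrast of 4 groups in the same fit.

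Alternatives were fixed before the data were examined: RLE in place of TMM factors, no count filter, DESeq2 1.42.0, limma 3.58.1 on log2(TPM + 1), only the compared groups in the fit, the clone or replicate number as a block, and each library left out in turn. In the last of these an arm of 2 keeps a lone library, which is assumed to vary like the other groups. The comparison of MAVS-knockout clones with the 1-day controls, the fits without clone 13 and the overlap with the Cre difference were chosen after seeing the data.

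Gene lists were written before the data were examined. They cover interferon-stimulated genes (74), interferon ligands and receptors (16), antigen presentation (22), cytosolic RNA sensing (25), cytosolic DNA sensing (15), NF-kB targets (37), cytokines and chemokines (34), p53 targets (57), cell cycle and E2F targets (56), integrated stress response (36), unfolded protein response (18), end joining and DNA-PK (16), homologous recombination and alternative end joining (25), telomere maintenance (16), ribosome biogenesis (36), ribosomal proteins (40), cell death (22), aryl hydrocarbon receptor targets (11), mitochondrially encoded genes (15), 7SL and other polymerase III transcripts (15), retroelement silencing (18), colon epithelial markers (20), HEK293 markers (18), blood and stromal markers (18) and reference genes (18). Lists with at least 5 tested members were tested with camera in limma, with the preset inter-gene correlation of 0.01 and with an estimated one. Of 178 list tests called with the preset value, 61 were called with the estimated one. Counts adjusted over the list alone use the p-values of the list's members only. List medians were also computed with members at 0 in 1 group set to their bound.

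The genes named in the text were chosen by a rule fixed before the data were examined. It takes XRCC5, XRCC6, PRKDC and MAVS, the 5 strongest called genes per direction with an average log2 CPM of at least 1 and the same direction in every pair, the 4 smallest p-values in each list with at least 2 called members, and 18 genes of interferon signalling, p53, cell cycle and stress. Of the genes the rule gave, those described best by their list are named, and some are not reported here. The genes EIF3B, MRPS35 and CAD follow this rule at 1 day and are named in further comparisons because their values there were seen.

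Steps that test many genes were run on counts simulated from the real means and library sizes with 200 changed genes. In the 4-day comparison, run on 17978 genes, edgeR found 48.4% of 2-fold and 73.5% of 4-fold changes with 0.84% of calls false. At 1 day (17982 genes) it found 38.3% and 64.6% with 1.96% false, for the MAVS difference 31.2% and 64.3% with 3.12% false, after Ku86 excision 78.6% and 94.8% with 6.63% false, and after Ku70 withdrawal 72.7% and 91.8% with 5.81% false. Camera found 5 of 5 changed lists and called 0 unchanged ones, but genes were simulated without correlation, so the preset one went untested. The HCT116 libraries fell into 2 sets on the first principal component (43.8% of variance). The first set of 18 libraries (2-, 4- and 6-day IAA with its controls and the 4-day inhibitor arms) had 64.1 to 71.1% of genes at 0, and the second set of 22 had 57.8 to 62.5%. Each tested response lies within 1 set, but the MAVS baseline and difference compare across both sets.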

Results

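Gene expression was measured by RNA sequencing in 46 libraries from human cell lines in which Ku, the ring-shaped Ku70/Ku80 dimer that binds DNA ends, was removed by 3 routes. HCT116 colon carcinoma clones carried Ku80 fused to an auxin-inducible degron. They received 100 µM indole-3-acetic acid (IAA) with 0.5 µg/mL doxycycline and their controls DMSO, so IAA against control mixes both compounds with Ku80 loss. These clones gave 2 libraries per group at 1 day, 3 per group at 2, 4 and 6 days, 2 and 3 per group at 2 and 4 days on a CDK4/6 inhibitor, and 3 per group at 4 days in clones that also lacked MAVS, the adaptor of the RIG-I-like RNA sensors. Further HCT116 cells (Ku86flox/-) with 1 floxed XRCC5 allele received 50 nM 4-hydroxytamoxifen (4OHT) or ethanol, with or without Cre recombinase, in 2 libraries per group. HEK293 clones in which Ku70 depended on doxycycline were compared with and without the drug after 8 days, with 3 clones per arm. Among the degron libraries, the 2-day DMSO controls held 10.1, 13.7 and 9.96 M (mega) counts and the 6-day libraries 45.7, 21.3 and 31.5 M. Low genes were thus measured less precisely in these controls than at 6 days. The other depths by clone were 15.1, 14.2 and 10 M after IAA at 2 days and 21.8, 17.1 and 12.8 M at 4 days. With the inhibitor for 4 days they were 17.9, 22.1 and 20.3 M without IAA and 11.9, 18.3 and 9.53 M with it. MAVS-knockout clones held 14.8, 12.7 and 13.8 M with DMSO and 15.9, 14.1 and 15 M with IAA, and the 1-day and 2-day inhibitor libraries 12.7 to 19.2 M. The Ku86flox/- libraries held 13 to 17.6 M, and in HEK293 the clones SB, Sa11 and TI held 24.8, 23.6 and 28.5 M with doxycycline and 19.6, 22.8 and 23.7 M without it. Levels are counts per M (CPM) with their SD over libraries, and changes are log2 fold changes ± standard error unless another unit is given.

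XRCC5, which encodes Ku80 (also called Ku86), fell in Cre-expressing cells from 256 and 259 CPM with ethanol to 24.9 and 30.7 CPM with 4OHT. Without Cre it read 236 and 252 CPM with ethanol and 237 and 244 CPM with 4OHT. XRCC6, which encodes Ku70, fell in HEK293 from 3006 ± 657 CPM (SD, n = 3; range 2269 to 3529) with doxycycline to 454 ± 137 CPM without it (range 339 to 605). Each HEK293 clone served as its own control. MAVS read 139 ± 27.4 CPM in DMSO-treated MAVS-knockout clones and 169 ± 20.2 CPM after IAA, with the 6 knockout libraries between 108 and 184 CPM. In the degron clones with intact MAVS no library read under 262 CPM, and the 2-day DMSO group read 324 ± 14.5 CPM. In the degron clones IAA removes the Ku80 protein, so XRCC5 mRNA is no check of depletion there. XRCC5 read 290.1 ± 9.54 CPM in the 2-day DMSO group and 216 ± 13.1, 205 ± 34.6 and 246 ± 51.3 CPM after 2, 4 and 6 days of IAA. It read 367 ± 44.3 and 336 ± 9.52 CPM without and with IAA at 1 day. With the inhibitor, XRCC5 read 353 ± 10.0 and 315 ± 3.82 CPM without and with IAA at 2 days, and 312 ± 44.3 and 264 ± 10.9 CPM at 4 days. In MAVS-knockout clones it read 214 ± 10.9 CPM with DMSO and 211 ± 15 CPM with IAA, and in HEK293 843 ± 194 and 978 ± 387 CPM with and without doxycycline.

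One day of IAA asked which transcripts move first. EIF3B, a subunit of a translation initiation factor, fell from 616 ± 14.1 to 216 ± 20.5 CPM (SD, n = 2 per group), a log2 change of -1.51 ± 0.19. MRPS35, a mitochondrial ribosomal protein, fell by 1.22 ± 0.15 on the log2 scale, and both had an edgeR adjusted p = 0.000115 that passed without each of the 4 libraries in turn. CAD, the multifunctional enzyme of pyrimidine synthesis, changed by -0.96 ± 0.14 (edgeR adjusted p = 0.00122), a call that was lost without the IAA library of clone 1 or the DMSO library of clone 9, and with limma on TPM values. None of the 72 interferon-stimulated genes tested was called by edgeR over all genes, while 8 rose when adjusted over the list alone, 18 had an unadjusted p under 0.05, and DESeq2 called 2 and limma 0. Their median log2 change was 0.375, or 0.386 with members at 0 in 1 group set to their bound (camera adjusted p = 2.7e-06, but adjusted p = 0.234 with an estimated correlation). The RNA sensor RIGI read a log2 change of 0.39 ± 0.32 (edgeR adjusted p = 0.995). Ribosome biogenesis genes had a median of -0.40, with 1 of 36 called down and 7 down when adjusted over the list alone (camera adjusted p = 3.37e-24, and adjusted p = 0.123 with an estimated correlation). Across 18877 genes edgeR called 22 up and 13 down (62.9% up, against 48 with RLE factors, 80 with limma on TPM values and 49.6 without the count filter). The total of 35 ran from 15 with limma to 1607 with only these 4 libraries in the fit, and was 107 with the clone as a block (2 of them interferon-stimulated). Without the DMSO or IAA library of clone 1 the count was 4 and 3, and without those of clone 9 it was 3 and 8.

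At 2 days of IAA proliferation genes fell. Of the 56 cell cycle and E2F target genes, 54 fell (55 adjusted over the list alone) with a median log2 change of -1.05 (camera adjusted p = 2.72e-51, and 0.0112 with an estimated correlation). Among them HELLS changed by -1.92 ± 0.16, MCM7 by -1.25 ± 0.13, PCNA by -1.09 ± 0.11, UHRF1 by -1.21 ± 0.12 and cyclin CCNA2 by -1.22 ± 0.22. Homologous recombination genes fell in 21 of 25 (22 adjusted over the list alone; median -0.88, camera adjusted p = 0.00971 with an estimated correlation). EXO1 stood at -1.44 ± 0.19 and FANCD2 at -1.42 ± 0.18. Ribosome biogenesis genes fell in 35 of 36 (35 over the list alone; median -0.78), among them NCL at -0.96 ± 0.13, NOP56 at -1.19 ± 0.14 and POLR1B at -1.08 ± 0.12 (camera adjusted p = 2.66e-27, but adjusted p = 0.0579 with an estimated correlation). Ribosomal protein genes fell in 15 of 40 (22 adjusted over the list alone; camera adjusted p = 3.72e-09, but adjusted p = 0.173 with an estimated correlation). EIF3B now read -2.64 ± 0.16 (edgeR adjusted p = 3.85e-11).

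Interferon-stimulated genes rose in 30 of 72 and fell in 1 at 2 days of IAA (36 and 1 adjusted over the list alone). Their median was 0.75, or 0.77 with members at their bound (camera adjusted p = 5.25e-12, but adjusted p = 0.0811 with an estimated correlation). SAMD9 rose by 1.93 ± 0.22, the RNA sensor RIGI by 1.71 ± 0.24, the transcription factor STAT2 by 1.06 ± 0.12, PARP9 by 0.99 ± 0.14 and the ubiquitin-like modifier ISG15 by 1.21 ± 0.28. IFIT1, which binds foreign RNA, read 0.89 ± 0.39 (edgeR adjusted p = 0.116), and was called with the clone as a block, without the count filter and with only the compared groups in the fit. Antigen presentation genes rose in 10 of 21 (11 adjusted over the list alone), with HLA-E at 0.88 ± 0.080 (camera adjusted p = 7.72e-06, but adjusted p = 0.0811 with an estimated correlation). Among 56 p53 targets 17 rose and 1 fell (21 and 2 adjusted over the list alone), including TP53INP1 at 1.05 ± 0.15, GDF15 at 0.81 ± 0.18, TNFRSF10C at 1.37 ± 0.25 and GADD45A at 0.75 ± 0.15 (camera adjusted p = 0.000381, but adjusted p = 0.153 with an estimated correlation). The integrated stress response list held 2 risen and 12 fallen genes of 35 (3 and 13 adjusted over the list alone; camera adjusted p = 0.000201, but adjusted p = 0.173 with an estimated correlation). The amino acid synthesis and one-carbon genes MTHFD2 at -1.63 ± 0.16, PSAT1 at -1.70 ± 0.18 and ASNS at -1.55 ± 0.23 fell, while DDIT3 rose by 1.24 ± 0.23. CEMIP rose by 4.65 ± 0.45 and THSD7A was at least 104-fold higher (363 counts against 0). DHRS2 at -2.98 ± 0.66 and KRT20 at -2.25 ± 0.56 fell, as did XRCC6 at -0.71 ± 0.11 and PRKDC, the DNA-PK catalytic subunit, at -0.76 ± 0.15. In total 1721 genes rose and 1876 fell (47.8% up, against 68.8 with limma on TPM values), 387 and 346 of them at least 2-fold, and the named genes that changed had edgeR adjusted p up to 0.00524. Without the IAA library of clone 1 the total of 3597 became 2274, and the only DMSO control of the 2-, 4- and 6-day groups was collected at 2 days, so at 4 and 6 days time in culture differed along with depletion.

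At 4 days of IAA the interferon-stimulated genes stood highest among the lists. Of 72 tested, 67 rose (70 adjusted over the list alone), with a median log2 change of 2.42, or 2.37 with members at 0 in the controls set to their bound (camera adjusted p = 1.48e-52, and 0.000769 with an estimated correlation). IFI6, a mitochondrial interferon-induced protein, rose from 3.67 ± 1.03 to 219.8 ± 58.0 CPM (SD, n = 3), higher in each of the 3 clones and 60.6-fold on the fit (5.92 ± 0.28 on the log2 scale, edgeR adjusted p = 5.99e-14). IFIT1 rose from 3.93 ± 0.342 to 67.6 ± 14.4 CPM (4.11 ± 0.37), ISG15 by 3.09 ± 0.28, PARP9 by 3.18 ± 0.15 and its ubiquitin ligase partner DTX3L by 2.50 ± 0.12. OAS1, which makes the activator of RNase L, stood near the detection limit in the controls and rose by 7.34 ± 0.96. XAF1 and SAMD9L had 0 counts in the controls and were at least 42.4-fold and at least 40.4-fold higher. Cytosolic RNA sensing genes rose in 8 of 24 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000336, and 0.0311 with an estimated correlation). Among them RIGI rose by 3.56 ± 0.24, IFIH1 (MDA5) by 2.83 ± 0.22 and the RNA-activated kinase EIF2AK2 (PKR) by 1.37 ± 0.13. Antigen presentation genes rose in 15 of 21 (15 adjusted over the list alone; median 1.21, camera adjusted p = 0.00452 with an estimated correlation). HLA-B stood at 1.89 ± 0.13 and B2M at 1.28 ± 0.13. Of these genes OAS1 had the highest edgeR adjusted p, 1.18e-06.

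Proliferation genes fell at 4 days of IAA too. Cell cycle and E2F targets fell in 55 of 56 (55 adjusted over the list alone; median -1.76, camera adjusted p = 0.00452 with an estimated correlation). TK1 changed by -2.08 ± 0.14, HELLS by -2.26 ± 0.16, MCM7 by -1.79 ± 0.13, LMNB1 by -2.07 ± 0.15, CCNA2 by -2.22 ± 0.23 and MKI67 by -1.50 ± 0.21. Homologous recombination genes fell in 21 of 25 (22 adjusted over the list alone; median -0.99, camera adjusted p = 0.00472 with an estimated correlation). FANCD2 stood at -2.14 ± 0.18, and PARP1 fell by 1.17 ± 0.090. Cell death genes rose in 9 of 20 and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.00779, and 0.0281 with an estimated correlation). CFLAR stood at 1.46 ± 0.14. Among 56 p53 targets 28 rose and 5 fell (28 and 6 adjusted over the list alone; camera adjusted p = 0.000911, but adjusted p = 0.23 with an estimated correlation). GADD45A stood at 1.64 ± 0.15, ZMAT3 at 1.18 ± 0.16 and CDKN1A at 1.23 ± 0.20. The integrated stress response list split into 9 risen and 13 fallen of 35 (9 and 14 adjusted over the list alone). DDIT3 at 2.23 ± 0.23 and PPP1R15A at 2.35 ± 0.23 rose, and the serine synthesis enzymes PHGDH at -2.76 ± 0.20 and PSAT1 at -2.18 ± 0.18 fell. The median of that list was 0.14 as fitted and -0.04 with members at their bound, and camera gave the direction down (adjusted p = 0.168). Mitochondrially encoded genes rose in 12 of 15 (13 adjusted over the list alone; camera adjusted p = 5.35e-05, but adjusted p = 0.257 with an estimated correlation). MT-ATP6 stood at 1.67 ± 0.30 and MT-CO2 at 1.35 ± 0.25. The mitochondrially encoded genes took 8.97 ± 1.36% of counts (SD, n = 3) against 5.02 ± 0.74% in the controls. XRCC6 fell by 1.35 ± 0.11 and PRKDC by 0.82 ± 0.15, CYP24A1 fell by 3.46 ± 0.30, and THSD7A was at least 361-fold higher. For the genes named here as changed the edgeR adjusted p was at most 0.000122.

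At 4 days of IAA ribosome biogenesis held 1 risen and 24 fallen genes of 36 (1 and 27 adjusted over the list alone; camera adjusted p = 3.36e-09, but adjusted p = 0.23 with an estimated correlation). Ribosomal proteins held 3 and 10 of 40 (camera adjusted p = 0.00716, but adjusted p = 0.537 with an estimated correlation) and retroelement silencing factors 2 and 6 of 18 (camera adjusted p = 0.0366, but adjusted p = 0.114 with an estimated correlation and 0.083 with the clone as a block). Reference genes held 3 risen and 10 fallen of 18 with a median of -0.53 (camera adjusted p = 0.000911, but adjusted p = 0.23 with an estimated correlation). No camera test passed for NF-kB targets (14 risen and 3 fallen of 35, camera adjusted p = 0.0969) or cytokines and chemokines (4 risen of 16, 0.168). Nor did it for interferon ligands and receptors (0.0969), cytosolic DNA sensing (0.119), the unfolded protein response (0.45), end joining and DNA-PK (0.204), telomere maintenance (0.334), aryl hydrocarbon receptor targets (0.66) or 7SL and other polymerase III transcripts, read from poly-A libraries (0.291). The adjusted p was 0.0918 for colon epithelial, 0.832 for HEK293 and 0.168 for blood and stromal markers. Over all genes 3379 rose and 2819 fell (54.5% up, against 41.4 with limma on TPM values), 1297 and 1022 of them at least 2-fold.

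After 6 days of IAA, NF-kB targets and cytokines rose beside the interferon-stimulated genes. The latter rose in 68 of 72 (69 adjusted over the list alone; median 2.76, camera adjusted p = 0.000276 with an estimated correlation). IFI6 read 421 ± 69.3 CPM (SD, n = 3; 6.86 ± 0.29, 116-fold over the control, edgeR adjusted p = 2.88e-15), IFIT1 122 ± 32.4 CPM (4.96 ± 0.38), and ISG15, OAS1 and RIGI rose by 3.77 ± 0.28, 7.99 ± 0.95 and 3.98 ± 0.25. IFI44L had 0 counts in the controls and was at least 74-fold higher. NF-kB targets rose in 19 of 35 and fell in 2 (22 and 3 adjusted over the list alone; median 0.61, camera adjusted p = 0.00372 with an estimated correlation). Cytokines and chemokines rose in 6 of 16 (6 adjusted over the list alone; median 1.21, camera adjusted p = 0.0129 with an estimated correlation). The neutrophil attractants CXCL8 and CXCL1 rose by 4.84 ± 0.54 and 3.04 ± 0.73, CXCL16 by 1.36 ± 0.17, interleukin IL15 by 1.76 ± 0.34, RELB by 2.24 ± 0.24 and BIRC2 by 1.24 ± 0.14. CXCL8 read 0.471 CPM in the controls, 0.792 CPM at 4 days and 13.2 ± 6.07 CPM at 6 days. Among antigen presentation genes 16 of 21 rose (camera adjusted p = 0.00197 with an estimated correlation). HLA-B stood at 2.40 ± 0.14. Of these genes CXCL1 had the highest edgeR adjusted p, 0.00175.

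At 6 days of IAA 8 of 18 unfolded protein response genes rose (9 adjusted over the list alone; camera adjusted p = 0.00304, but adjusted p = 0.143 with an estimated correlation). DNAJB9 stood at 2.08 ± 0.17, HSPA5 at 1.00 ± 0.16 and XBP1 at 1.14 ± 0.19. The integrated stress response list held 14 risen and 7 fallen of 35, with DDIT3 at 2.57 ± 0.23, PPP1R15A at 2.98 ± 0.24, ATF3 at 2.16 ± 0.36 and SESN2 at 2.13 ± 0.20 risen and PHGDH at -2.74 ± 0.20 fallen (camera adjusted p = 0.0132, but adjusted p = 0.414 with an estimated correlation). Among 56 p53 targets 26 rose and 9 fell (28 and 10 adjusted over the list alone), including GADD45A at 1.98 ± 0.15, CDKN1A at 1.59 ± 0.20, MDM2 at 0.52 ± 0.12 and PMAIP1 at 1.63 ± 0.24 (camera adjusted p = 0.000337, but adjusted p = 0.143 with an estimated correlation). Cell death genes rose in 9 of 20 and fell in 1 (camera adjusted p = 0.0129 with an estimated correlation). Cell cycle and E2F targets fell in 54 of 56 (55 adjusted over the list alone; median -1.55, camera adjusted p = 0.00731 with an estimated correlation). TK1 stood at -1.99 ± 0.14 and HELLS at -2.55 ± 0.16. Mitochondrially encoded genes took 7.88% of counts against 5.02% in the controls and 4.62% at 2 days, and reference genes had a median of -0.418. CYP24A1 fell by 5.22 ± 0.33 and XRCC6 by 1.03 ± 0.11. In all 3351 genes rose and 3299 fell, 1272 and 1486 of them at least 2-fold, and the named genes that changed had edgeR adjusted p up to 0.00147.

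Set directly against 2 days of IAA, 6 days carried further rises in several groups. Interferon-stimulated genes rose in 61 of 72 and fell in 1 (64 and 1 adjusted over the list alone; median 1.91, camera adjusted p = 0.00012 with an estimated correlation), with IFI6 at 5.15 ± 0.26, IFIT1 at 4.07 ± 0.35 and OAS3 at 2.75 ± 0.13 (edgeR adjusted p = 9.93e-14). NF-kB targets rose in 19 of 35 (21 with 1 fallen over the list alone; camera adjusted p = 0.00288 with an estimated correlation), among them PLAU at 1.80 ± 0.17, BIRC3 at 1.84 ± 0.24 and NFKBIA at 1.23 ± 0.20. Cytokines and chemokines rose in 7 of 16 and fell in 1, with CXCL8 at 3.93 ± 0.50 (camera adjusted p = 0.00517 with an estimated correlation). Genes of antigen presentation rose in 14 of 21 (16 adjusted over the list alone), with HLA-B at 1.75 ± 0.13 (camera adjusted p = 0.00517 with an estimated correlation). The integrated stress response list rose in 22 of 35 and fell in 2 (22 and 3 adjusted over the list alone; median 1.05, camera adjusted p = 0.0376 with an estimated correlation). ATF4 stood at 1.60 ± 0.15, CEBPG at 1.72 ± 0.16, VEGFA at 1.07 ± 0.10 and PMAIP1 at 1.47 ± 0.24. Ribosome biogenesis genes, low at 2 days, rose in 30 of 36 (32 adjusted over the list alone), with RRP9 at 1.36 ± 0.19, RRP12 at 1.07 ± 0.16 and NOP56 at 0.95 ± 0.14 (camera adjusted p = 2.81e-18, but adjusted p = 0.0856 with an estimated correlation). Cell cycle genes rose in 2 and fell in 34 of 56 (2 and 39 adjusted over the list alone), with PLK1 at -1.43 ± 0.19 and cyclin CCNB2 at -1.41 ± 0.18 (camera adjusted p = 1.27e-11, but adjusted p = 0.21 with an estimated correlation). Over all genes 2410 rose and 2234 fell. The named genes had edgeR adjusted p up to 7.82e-05. The share up was 51.9% against 23.5 with limma on TPM values, which moved the median of all genes by -0.15.

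**Figure D1:**
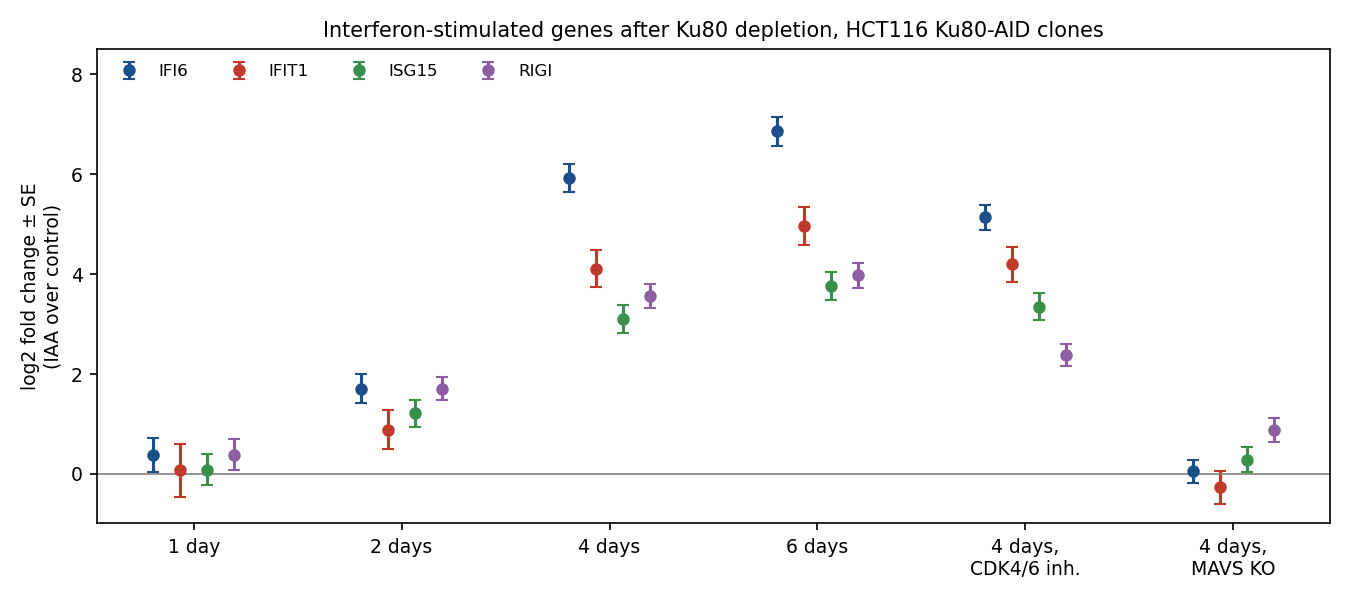
Log2 fold change (± SE from edgeR) of IFI6, IFIT1, ISG15 and RIGI on the vertical axis in 6 comparisons of IAA with its control, with 2 libraries per group at 1 day and 3 elsewhere. IFI6 stood at 5.92 after 4 days and at 5.14 with the CDK4/6 inhibitor, while IFIT1 stood at -0.27 in the MAVS-knockout clones.

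CDK4/6 inhibitors block entry into S phase, but how far this held here was not measured. After 2 days of IAA on the inhibitor, 8 of the 72 interferon-stimulated genes rose (20 adjusted over the list alone), with a median log2 change of 0.68, or 0.61 with members at their bound (camera adjusted p = 1.49e-25, and 0.0286 with an estimated correlation). IFI6 rose by 2.15 ± 0.29 and RIGI by 1.91 ± 0.29, while EIF3B changed by -1.43 ± 0.19 and MRPS35 by -1.06 ± 0.15. The edgeR adjusted p was 0.000588 for IFI6, EIF3B and MRPS35 and 0.00156 for RIGI (n = 2 clones per group). IFI6 passed without each library in turn. EIF3B was lost without the IAA library of clone 1, and MRPS35 and RIGI without that library or the control of clone 9. Among p53 targets 1 rose (7 adjusted over the list alone; camera adjusted p = 0.0365 with an estimated correlation), and among cell cycle genes 1 fell (19 adjusted over the list alone; median -0.49, camera adjusted p = 0.0493 with an estimated correlation). Over all genes 56 rose and 22 fell (71.8% up, against 54.4 with DESeq2 and 82.1 with limma on TPM values). The total of 78 became 165 with the clone as a block and ran from 28 with limma to 575 with only these 4 libraries. Without the control or IAA library of clone 1 it was 5 and 4, and without those of clone 9 it was 4 and 9, with 1, 1, 1 and 2 interferon-stimulated genes left.

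By 4 days on the inhibitor, IAA raised 67 of 72 interferon-stimulated genes (70 adjusted over the list alone; median 2.22, camera adjusted p = 1.13e-06 with an estimated correlation). IFI6 rose from 11.6 to 408 CPM in the mean of 3 clones (5.14 ± 0.26, edgeR adjusted p = 2.76e-13), IFIT1 by 4.20 ± 0.34, ISG15 by 3.35 ± 0.27, OAS3 by 2.43 ± 0.13 and the ISG15 protease USP18 by 2.81 ± 0.17. RNA sensing genes rose in 9 of 24 (10 adjusted over the list alone; camera adjusted p = 0.0077 with an estimated correlation). RIGI stood at 2.37 ± 0.22 and IFIH1 at 2.15 ± 0.20. Antigen presentation genes rose in 14 of 21 (median 0.76, camera adjusted p = 0.000145 with an estimated correlation). HLA-B stood at 1.43 ± 0.13 and the peptide transporter TAP1 at 1.34 ± 0.12. Cytokines and chemokines rose in 4 of 16 (6 adjusted over the list alone; camera adjusted p = 0.0178 with an estimated correlation) and cell death genes in 4 of 20 (6 over the list alone; camera adjusted p = 0.0178 with an estimated correlation). Cell cycle genes fell in 47 of 56 (53 adjusted over the list alone; median -0.90, camera adjusted p = 0.0143 with an estimated correlation). AURKB changed by -1.28 ± 0.16, HELLS by -1.10 ± 0.15 and CCNA2 by -1.22 ± 0.22. Homologous recombination genes fell in 12 of 25 (14 adjusted over the list alone; camera adjusted p = 0.021 with an estimated correlation). FANCD2 stood at -1.11 ± 0.18. Among 56 p53 targets 13 rose and 2 fell (18 and 3 adjusted over the list alone), with GDF15 at 1.51 ± 0.18 and GADD45A at 0.77 ± 0.15 (camera adjusted p = 8.22e-05, but adjusted p = 0.126 with an estimated correlation). DDIT3 rose by 1.47 ± 0.23, XRCC6 fell by 0.63 ± 0.11 and the mitochondrial ribosomal RNA MT-RNR2 fell by 0.83 ± 0.12. In all 1157 genes rose and 962 fell (54.6% up, against 80.4 with limma on TPM values), and the named genes that changed had edgeR adjusted p up to 0.00103. The total of 2119 became 1314 and 1260 without the control and the IAA library of clone 1, and 1359 without the IAA library of clone 7.

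Inhibitor libraries at 4 days without IAA were set against 2-day DMSO, so time in culture differed along with the drug. Cell cycle and E2F targets fell in 42 of 56 and rose in 1 (49 and 1 adjusted over the list alone; median -0.66, camera adjusted p = 0.0298 with an estimated correlation). The E2F repressor E2F8 stood at -1.63 ± 0.17, EZH2 at -0.89 ± 0.10, CDC45 at -1.04 ± 0.16 and PCNA at -0.70 ± 0.10. Mitochondrially encoded genes rose in 15 of 15 (15 adjusted over the list alone; median 1.37, camera adjusted p = 0.021 with an estimated correlation). MT-CYB stood at 1.49 ± 0.23, MT-RNR2 at 1.71 ± 0.12 and MT-ND2 at 1.40 ± 0.21. Mitochondrially encoded genes took 11.4 ± 4.07% of counts (SD, n = 3; range 8.67 to 16) against 5.02 ± 0.74% in the controls. Interferon-stimulated genes rose in 25 of 72 (38 with 2 fallen over the list alone; median 0.63, or 0.64 with members at their bound, camera adjusted p = 0.0298 with an estimated correlation). IFITM1, which blocks virus entry, rose by 3.07 ± 0.45, IFIT2 by 2.45 ± 0.38, DTX3L by 1.13 ± 0.12, PARP9 by 1.28 ± 0.14 and RIGI by 1.64 ± 0.24. Colon epithelial markers rose in 4 of 12 (4 adjusted over the list alone; camera adjusted p = 0.0298 with an estimated correlation). KRT18 stood at 1.00 ± 0.12 and KRT8 at 0.88 ± 0.14. Cell death genes rose in 5 of 20 (7 adjusted over the list alone; camera adjusted p = 0.0137 with an estimated correlation). TP53INP1 rose by 1.04 ± 0.15 and PLK2 by 1.59 ± 0.34, within a p53 list of 10 risen and 3 fallen genes (camera adjusted p = 0.0105, but adjusted p = 0.35 with an estimated correlation). ASNS at -1.36 ± 0.23 and PHGDH at -1.24 ± 0.18 fell, KLK5 rose by 4.74 ± 0.56 and TRIM9 fell by 2.56 ± 0.30. Over all genes 726 rose and 725 fell (50% up, against 13.5 with limma on TPM values, which moved the median of all genes by -0.14), and the named genes that changed had edgeR adjusted p up to 0.00348. The total of 1451 became 767 and 787 without the DMSO libraries of clones 7 and 9 and 948 without the inhibitor library of clone 9, and 15 interferon-stimulated genes remained called without the DMSO library of clone 7.

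The response to IAA with the inhibitor minus that without it tested where the inhibitor altered the response at 4 days. The control arm was collected at 4 days with the inhibitor and at 2 days without it, so time in culture also enters this difference. Cell cycle genes fell less with the inhibitor, but their lower start (inhibitor alone, median -0.66) was not separated. Of 56, 28 had a positive difference (44 adjusted over the list alone, median 0.86, camera adjusted p = 0.0431 with an estimated correlation). MCM2 differed by 1.32 ± 0.19, MCM7 by 1.28 ± 0.18, TK1 by 1.22 ± 0.19 and UHRF1 by 1.06 ± 0.17. The difference was positive for 7 of 25 homologous recombination genes (8 adjusted over the list alone; camera adjusted p = 0.0431 with an estimated correlation). Mitochondrially encoded genes had negative differences in 14 of 15 (15 adjusted over the list alone; median -1.55, camera adjusted p = 0.0431 with an estimated correlation). MT-CO2 stood at -1.87 ± 0.35 and MT-RNR2 at -1.14 ± 0.17. Their share of counts went from 11.4 to 8.33% with the inhibitor and from 5.02 to 8.97% without it. With the inhibitor clone 9 made this fall (16 to 7.08%), while the share went from 9.4 to 9.76% in clone 1 and from 8.67 to 8.15% in clone 7. PHGDH differed by 1.90 ± 0.27, PSAT1 by 1.56 ± 0.25, PARP1 by 0.73 ± 0.13 and XRCC6 by 0.72 ± 0.15. Among 72 interferon-stimulated genes 1 differed upwards and 2 downwards (1 and 2 adjusted over the list alone), with a median of -0.23, or -0.20 with members at their bound (camera adjusted p = 0.147). These were UBA7, the ISG15-activating enzyme, at 3.22 ± 0.76 (edgeR adjusted p = 0.014), PARP9 at -0.98 ± 0.20 (0.00413) and DTX3L at -0.68 ± 0.16 (0.0158). PARP9 and DTX3L were not called by limma, nor UBA7 with only these 12 libraries in the fit, and with the clone as a block 5 of the list were called (1 up, 4 down). Over all genes 414 differences were positive and 472 negative (46.7% up, against 84.3 with limma on TPM values, which moved the median by 0.18), and the named genes that changed had edgeR adjusted p up to 0.0158. The total of 886 was 410 and 511 without the DMSO libraries of clones 9 and 7, 526 without the inhibitor control of clone 9, 498, 590 and 538 without the inhibitor and IAA libraries of clones 1, 7 and 9, and 1466 without the 4-day IAA library of clone 1. Without the 4-day IAA library of clone 9, 5 interferon-stimulated genes were called.

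In clones without MAVS, 4 days of IAA left most interferon-stimulated genes uncalled. Of 72, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with a median log2 change of 0.19 with or without members at their bound (camera adjusted p = 0.0488, but adjusted p = 0.774 with an estimated correlation). IFIT1 read -0.27 ± 0.33 (edgeR adjusted p = 0.775, and a positive 0.10 without the IAA library of clone 13), ISG15 0.28 ± 0.25 (0.636) and OAS1 0.47 ± 0.78 (0.848). The called members included DTX3L, which rose by 0.57 ± 0.12 and ZNFX1, an antiviral helicase, by 0.41 ± 0.099, calls that ended with only these 6 libraries in the fit for DTX3L and without clone 13 in both arms for ZNFX1. DDIT3 rose by 2.06 ± 0.22 (edgeR adjusted p = 1.72e-06) and TIGAR by 0.88 ± 0.14. Antigen presentation genes rose in 4 of 21 (8 adjusted over the list alone; camera adjusted p = 8.21e-05, but adjusted p = 0.231 with an estimated correlation) and p53 targets in 9 of 56, with 2 fallen (17 and 3 over the list alone; camera adjusted p = 0.00169, but adjusted p = 0.284 with an estimated correlation). Cell cycle genes fell in 13 of 56 (30 adjusted over the list alone; median -0.39, camera adjusted p = 1.15e-15, but adjusted p = 0.231 with an estimated correlation). HELLS changed by -1.07 ± 0.16, MCM7 by -0.66 ± 0.13 and TK1 by -0.67 ± 0.13. CEMIP rose by 4.08 ± 0.38 and NRP1 by 2.37 ± 0.36, while SUSD2 at -3.33 ± 0.56, DHRS2 at -2.83 ± 0.60, CYP24A1 at -2.43 ± 0.28, PHGDH at -1.12 ± 0.18 and TFRC at -0.84 ± 0.13 fell. EIF3B read 357 CPM with DMSO and 120.1 CPM with IAA. In all 893 genes rose and 595 fell (60% up, against 75.8 with limma on TPM values), and the named genes that changed had edgeR adjusted p up to 0.00895. The total of 1488 was 775 with only these 6 libraries and 927, 892 and 923 without the DMSO library of clone 1, 13 or 15. With those left out 4, 3 and 4 interferon-stimulated genes were called, and 3 without the IAA library of clone 15.

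The 4-day response in MAVS-knockout clones minus that in clones with MAVS tested the loss itself. The difference was negative for 56 of 72 interferon-stimulated genes (65 adjusted over the list alone), with a median of -2.07, or -2.06 with members at their bound (camera adjusted p = 2.23e-91, and 1.31e-05 with an estimated correlation). IFI6 differed by -5.87 ± 0.37 (edgeR adjusted p = 7.33e-11), IFITM1 by -5.71 ± 0.58, IFIT1 by -4.37 ± 0.50, OAS1 by -6.87 ± 1.35, ISG15 by -2.81 ± 0.37, PARP9 by -2.70 ± 0.20 and OAS3 by -2.31 ± 0.18. MX1, an antiviral GTPase, read -1.52 ± 0.63 (edgeR adjusted p = 0.183). RNA sensing genes had 6 negative differences of 24 (8 with 1 positive over the list alone; camera adjusted p = 0.00661 with an estimated correlation). RIGI stood at -2.69 ± 0.34, IFIH1 at -2.68 ± 0.30 and EIF2AK2 at -1.47 ± 0.18. Antigen presentation genes had 11 of 21 (12 adjusted over the list alone; median -0.93, camera adjusted p = 0.0019 with an estimated correlation). HLA-B stood at -1.49 ± 0.18, B2M at -0.97 ± 0.18 and HLA-E at -0.95 ± 0.11. Proliferation genes differed in the other direction. Of 56 cell cycle genes 48 had a positive difference (55 adjusted over the list alone; median 1.25, camera adjusted p = 0.0019 with an estimated correlation). CDCA3 stood at 2.06 ± 0.25, PLK1 at 1.95 ± 0.27, AURKA at 1.67 ± 0.23, CCNA2 at 1.61 ± 0.31, TK1 at 1.42 ± 0.19 and UHRF1 at 1.29 ± 0.17. Homologous recombination genes had 10 of 25 (21 adjusted over the list alone; camera adjusted p = 0.00337 with an estimated correlation). FANCD2 stood at 1.32 ± 0.25. PARP1 differed by 0.67 ± 0.13, PHGDH by 1.64 ± 0.26 and XRCC6 by 0.90 ± 0.15. Mitochondrially encoded genes had 6 negative differences of 15 (12 adjusted over the list alone; camera adjusted p = 1.04e-09, but adjusted p = 0.121 with an estimated correlation), their share of counts going from 6.29 to 6.14% without MAVS. Over all genes 464 differences were positive and 451 negative (50.7% up, against 80.5 with limma on TPM values, which moved the median by 0.15), and the named genes that changed had edgeR adjusted p up to 0.00244. The total of 915 was 529 without the 2-day DMSO library of clone 9 and 570 without the MAVS-knockout DMSO library of clone 1. The MAVS-knockout libraries came from other clones and belonged to another set of libraries than the 2- to 6-day degron libraries, but both arms of each response came from 1 set. The DMSO arm was collected at 4 days in MAVS-knockout clones and at 2 days in clones with MAVS.

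Without IAA, MAVS-knockout clones differed from the other degron clones in 8702 genes, 4633 higher and 4069 lower (53.2% up, against 38.4 with limma on TPM values, which moved the median by -0.16). MAVS itself differed by -1.23 ± 0.15 (edgeR adjusted p = 3.28e-07). HLA-B at 1.43 ± 0.13 and HLA-E at 1.13 ± 0.080 were higher within an antigen presentation list of 13 higher and 1 lower gene (camera adjusted p = 2.61e-05, but adjusted p = 0.272 with an estimated correlation). HELLS at -2.06 ± 0.16 and BRCA2 at -1.92 ± 0.19 were lower. Interferon-stimulated genes were higher in 23 and lower in 9 of 72 (22 and 9 adjusted over the list alone), with a median of 0.40, or 0.25 with members at their bound (camera adjusted p = 0.168). This comparison follows the set of libraries, so clone, set and MAVS cannot be told apart in it. Against the DMSO libraries of the 1-day experiment, which are in the same set, 6168 genes differed, 2477 higher and 3691 lower, while 3252 of the 8702 calls were kept and 427 were called in the opposite direction.

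In Cre-expressing Ku86flox/- cells, 4OHT lowered XRCC5 by 3.21 ± 0.079 on the log2 scale (9.28-fold lower, edgeR adjusted p = 6.31e-12, n = 2 per group). Interferon-stimulated genes rose in 65 of 71 (67 with 1 fallen over the list alone; median 1.24, camera adjusted p = 0.00217 with an estimated correlation). IFI6 rose by 2.46 ± 0.061 (edgeR adjusted p = 7.69e-12), IFIT1 from 27.6 to 158 CPM (2.52 ± 0.067), OAS1 by 2.23 ± 0.073 and ISG15 by 2.09 ± 0.086. RNA sensing genes rose in 12 of 24 and fell in 3 (camera adjusted p = 0.0477 with an estimated correlation). RIGI stood at 1.90 ± 0.075, IFIH1 at 1.37 ± 0.090 and TLR3 at 2.29 ± 0.15. Antigen presentation genes rose in 15 of 20 and fell in 1, with TAP1 at 1.15 ± 0.069 and HLA-B at 0.88 ± 0.053 (camera adjusted p = 0.000496, but adjusted p = 0.161 with an estimated correlation). Targets of p53 rose in 49 of 55 and fell in 3 (50 and 3 adjusted over the list alone; median 0.86, camera adjusted p = 0.00984 with an estimated correlation). TP53I3 rose by 2.46 ± 0.076, TP53INP1 by 1.99 ± 0.072, CDKN1A by 1.73 ± 0.056, GDF15 by 1.46 ± 0.073, BTG2 by 1.36 ± 0.057 and MDM2 by 1.34 ± 0.063. Cell death genes rose in 13 of 20 and fell in 1, with BIK at 1.98 ± 0.095 and PMAIP1 at 1.44 ± 0.070 (camera adjusted p = 0.000266, but adjusted p = 0.0537 with an estimated correlation). Cell cycle genes fell in 55 of 56 (median -2.30, camera adjusted p = 0.00217 with an estimated correlation). RRM2 stood at -2.60 ± 0.055, LMNB1 at -2.80 ± 0.067, CENPF at -2.47 ± 0.063, MKI67 at -3.13 ± 0.085 and CCNA2 at -2.75 ± 0.11. Homologous recombination genes fell in 21 of 25 (median -1.61, camera adjusted p = 0.0307 with an estimated correlation). EXO1 stood at -2.63 ± 0.094 and FANCD2 at -2.34 ± 0.080. CPA4 rose by 3.66 ± 0.058, GALNT5 by 3.76 ± 0.073 and KRTAP3-1 by 4.79 ± 0.11. PHGDH at -2.58 ± 0.096, TERT at -2.42 ± 0.24, VIM at -3.08 ± 0.26, XRCC6 at -0.60 ± 0.047 and PRKDC at -0.75 ± 0.046 fell. Mitochondrially encoded genes rose in 12 of 15 and fell in 1 (camera adjusted p = 0.00282, but adjusted p = 0.342 with an estimated correlation), taking 9.84% of counts against 7.36%. Over all 16726 genes 4424 rose and 4605 fell (49% up, against 37 with limma on TPM values), 838 and 1399 of them at least 2-fold, and the named genes that changed had edgeR adjusted p up to 2.03e-06.

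Without Cre, 4OHT measured the compound itself against ethanol. Genes that fell included FOS at -3.67 ± 0.24, FOSB at -3.96 ± 0.29, DUSP1 at -2.54 ± 0.12, CCN1 at -2.83 ± 0.13, KLF6 at -0.95 ± 0.050 and JUNB at -0.86 ± 0.070 (edgeR adjusted p = 1.64e-06 for FOS). NF-kB targets rose in 2 and fell in 11 (2 and 14 adjusted over the list alone; camera adjusted p = 0.049 with an estimated correlation). Integrated stress response genes rose in 1 and fell in 13 of 34 (2 and 17 adjusted over the list alone; camera adjusted p = 0.0446 with an estimated correlation). ATF3 stood at -1.45 ± 0.098 and PPP1R15A at -1.56 ± 0.078. Among 55 p53 targets 2 rose and 15 fell (3 and 17 adjusted over the list alone; camera adjusted p = 0.049 with an estimated correlation). PLK2 stood at -1.06 ± 0.059 and GDF15 at -0.59 ± 0.074. Unfolded protein response genes fell in 7 (12 adjusted over the list alone; camera adjusted p = 0.0446 with an estimated correlation). Interferon-stimulated genes rose in 17 of 71 (21 adjusted over the list alone; median 0.26, or 0.23 with members at their bound, camera adjusted p = 0.0446 with an estimated correlation), with IFIT1 at 0.78 ± 0.13, BST2 (tetherin) at 0.75 ± 0.12, DTX3L at 0.75 ± 0.085 and PARP9 at 0.57 ± 0.082. Cyclin CCNE2 rose by 1.13 ± 0.093. In all 1215 genes rose and 1077 fell (53% up, against 73.7 with limma on TPM values and 39.2 with DESeq2), and the named genes that changed had edgeR adjusted p up to 0.00204. The total of 2292 was 612 with limma and 773 and 1097 without 4OHT library 1 or 2, which left 8 and 11 interferon-stimulated genes called. The library names mark the ethanol controls of both cell types as day 0, whereas the treatment labels give 4 days, so the time since plating or feeding of these controls is uncertain.

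The 4OHT response with Cre minus that without it removes what the compound does alone. It leaves Cre activity, not controlled with intact Ku, mixed with Ku86 loss. XRCC5 differed by -3.19 ± 0.10 (edgeR adjusted p = 2.44e-10). Interferon-stimulated genes had 45 positive and 1 negative difference of 71 (47 and 1 adjusted over the list alone), with a median of 0.90, or 0.87 with members at their bound (camera adjusted p = 3.29e-15, and 0.0177 with an estimated correlation). ISG15 differed by 2.18 ± 0.14, IFI6 by 2.16 ± 0.12, OAS1 by 1.75 ± 0.21, IFIT1 by 1.74 ± 0.15, RIGI by 1.63 ± 0.13 and IFIH1 by 1.13 ± 0.15. Targets of p53 had 47 positive and 2 negative differences of 55 (48 and 3 adjusted over the list alone; median 1.02, camera adjusted p = 0.00803 with an estimated correlation). GDF15 stood at 2.04 ± 0.10, CDKN1A at 1.95 ± 0.078, BTG2 at 1.70 ± 0.082 and MDM2 at 1.42 ± 0.090. Cell cycle genes had negative differences in 56 of 56 (median -2.34, camera adjusted p = 0.00197 with an estimated correlation). LMNB1 stood at -2.90 ± 0.087, MKI67 at -2.96 ± 0.11, RRM2 at -2.72 ± 0.073 and MCM6 at -2.19 ± 0.073. Homologous recombination genes had 20 of 25 (21 adjusted over the list alone; median -1.83, camera adjusted p = 0.0163 with an estimated correlation). EXO1 stood at -2.92 ± 0.12. Antigen presentation genes had 11 positive differences, with TAP1 at 1.27 ± 0.10 (camera adjusted p = 0.000297, but adjusted p = 0.143 with an estimated correlation), and NF-kB targets 15 positive and 3 negative (camera adjusted p = 0.00275, but adjusted p = 0.168 with an estimated correlation). ATF3 differed by 2.24 ± 0.13, CPA4 by 4.06 ± 0.080, PHGDH by -2.27 ± 0.13 and EIF3B by -0.86 ± 0.071. Over all genes 3141 differences were positive and 3744 negative (45.6% up, against 25.1 with limma on TPM values, which moved the median by -0.15), and the named genes that changed had edgeR adjusted p up to 5.27e-05.

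In HEK293, 8 days without doxycycline lowered XRCC6 by 2.73 ± 0.26 on the log2 scale (6.62-fold lower, edgeR adjusted p = 0.00101, n = 3 clones per arm). Integrated stress response genes rose in 18 of 36 (20 with 1 fallen over the list alone; median 0.58), with ATF3 at 1.73 ± 0.15, DDIT3 at 1.56 ± 0.17, CEBPB at 1.38 ± 0.15 and INHBE at 4.11 ± 0.46 (camera adjusted p = 1.21e-08, but adjusted p = 0.711 with an estimated correlation). NF-kB targets rose in 14 of 34 (17 adjusted over the list alone), with the chemokines CXCL1 at 3.29 ± 0.52 and CXCL2 at 3.06 ± 0.47, NFKBIB at 1.53 ± 0.13, GADD45B at 2.70 ± 0.35, NFKB1 at 1.18 ± 0.14 and RIPK2 at 1.04 ± 0.15 (camera adjusted p = 1.92e-07, but adjusted p = 0.711 with an estimated correlation). Ribosome biogenesis genes rose in 23 of 36 (27 adjusted over the list alone; median 0.66), with RRP12 at 1.22 ± 0.12, PNO1 at 1.18 ± 0.18 and NOP2 at 1.15 ± 0.17 (camera adjusted p = 1.95e-13, but adjusted p = 0.711 with an estimated correlation). Among 55 p53 targets 9 rose and 2 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.49). GADD45A stood at 1.16 ± 0.20, AEN at 1.07 ± 0.16, SERTAD1 at 2.25 ± 0.23 and PPM1D at 0.78 ± 0.12. FOS rose by 3.26 ± 0.19. Mitochondrially encoded genes took 1.42% of counts with doxycycline and 0.929% without it.

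Interferon-stimulated genes in HEK293 rose in 1 and fell in 10 of 66 after doxycycline was withdrawn (1 and 8 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.191). BST2 fell by 1.89 ± 0.29 and PARP14 by 0.79 ± 0.16, the latter not called by limma. IFIT2 was called with a rise of 1.86, and RIGI, of the RNA sensing list, rose by 0.99 ± 0.19. IFIT1 read -0.54 ± 0.26 (edgeR adjusted p = 0.169). Antigen presentation genes fell in 6 of 18 (7 adjusted over the list alone; camera adjusted p = 0.0124, but adjusted p = 0.741 with an estimated correlation). STING1, the adaptor of cytosolic DNA sensing, changed by -1.24 ± 0.23. Cell cycle genes split into 5 risen and 6 fallen (camera adjusted p = 0.454), with E2F8 at 0.81 ± 0.13 and CDC25A at 0.82 ± 0.14. End joining genes rose in 3 and fell in 1 of 16 and homologous recombination genes in 5 and 3 of 25 (camera adjusted p = 0.437 for both). LIG4 at 0.81 ± 0.13, DCLRE1C (Artemis) at 1.11 ± 0.15 and EXO1 at 0.96 ± 0.18 rose while FANCD2 at -0.69 ± 0.11 fell. PIR at -3.26 ± 0.35, DERL3 at -3.35 ± 0.38, GSTP1 at -3.07 ± 0.51, EFEMP1 at -3.20 ± 0.63, EPCAM at -1.61 ± 0.18 and EIF3B at -0.97 ± 0.17 fell. The named genes that changed, IFIT2 aside, had edgeR adjusted p up to 0.00929. Over 15549 genes 1731 rose and 1695 fell, and with the clone as a block 5404 were called, 2 and 17 of the interferon-stimulated genes among them up and down. The total of 3426 was 2209 with limma and, without single libraries, 1164 and 1665 (Sa11 with and without doxycycline), 2126 (SB with) and 1524 (TI with). The 11 called interferon-stimulated genes became 2 and 6 without the Sa11 library with or without doxycycline, 5 and 6 without those of TI, and 17 without the SB library without doxycycline.

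The 3 routes of Ku removal were set against each other by the overlap of their calls, with Fisher's exact test over the genes tested in both. Ku80 depletion at 4 days and Ku86 excision shared 1719 risen genes of 16462 (862 for independent lists, odds ratio 4.48) and 1680 fallen genes (763, odds ratio 5.9). Their log2 changes correlated at r = 0.294 (rho = 0.366) across genes, which are not independent replicates. Ku80 depletion and Ku70 withdrawal shared 435 risen genes of 13363 (345 for independent lists, odds ratio 1.42, Fisher's exact adjusted p = 2.49e-08) and 388 fallen genes (304, odds ratio 1.43, Fisher's exact adjusted p = 3.21e-08), with r = 0.0515 across genes. With the clone as a block these were 585 (542, odds ratio 1.13, Fisher's exact adjusted p = 0.0205) and 617 (519, odds ratio 1.32). Ku86 excision and Ku70 withdrawal shared 540 risen (451, odds ratio 1.36) and 694 fallen genes (494, odds ratio 1.9) of 12640, with r = 0.0848. Among genes changed at least 2-fold, the last pair shared 13 risen genes against 10.5 for independent lists (odds ratio 1.26, Fisher's exact adjusted p = 0.422), and 15 against 8.18 with the Cre difference in place of excision (odds ratio 1.92, Fisher's exact adjusted p = 0.0314).

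**Figure D2:**
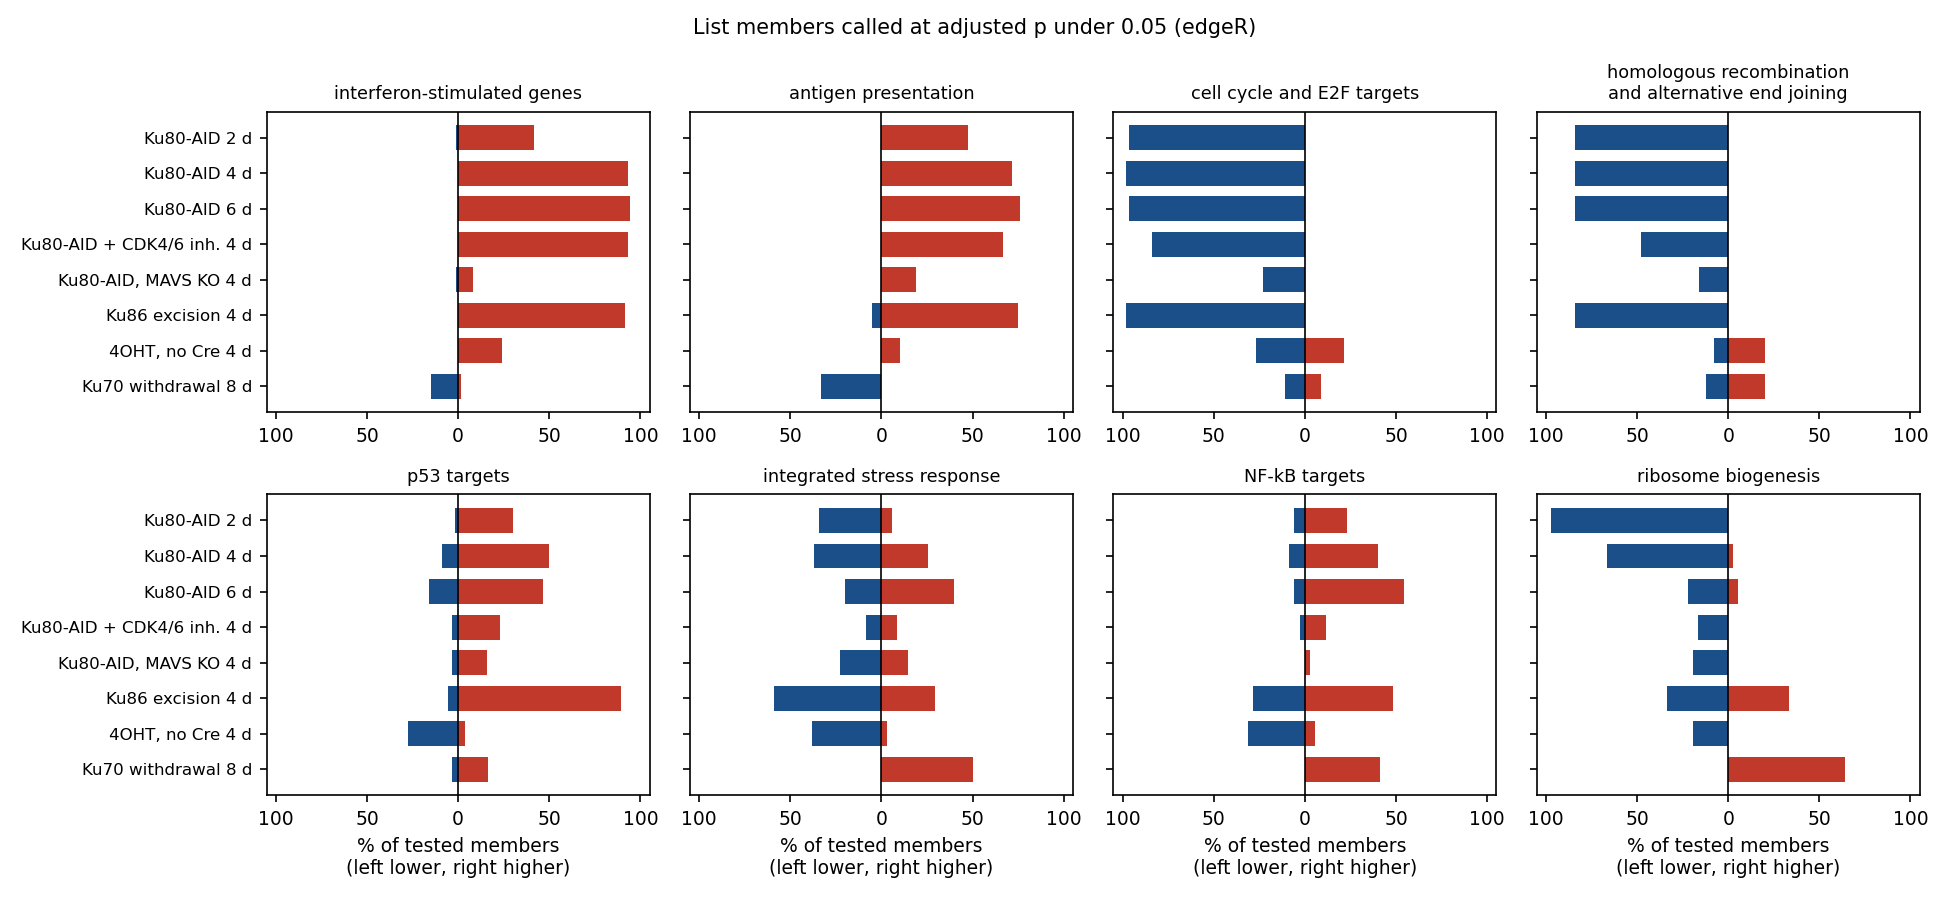
Share of the tested members of 8 gene lists called by edgeR (percent, risen to the right and fallen to the left of 0) in 8 comparisons. Interferon-stimulated genes rose in 67 of 72 after 4 days of IAA, in 6 of 72 in MAVS-knockout clones and in 1 of 66 after Ku70 withdrawal in HEK293.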

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

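The tests of the MAVS pattern were chosen after the result was seen, and the counts of other splits were planned. The 4-day IAA response differed with and without the CDK4/6 inhibitor in 886 genes (medians 0.855 for cell cycle and -1.55 for mitochondrially encoded genes). It differed between clones with and without MAVS in 915 genes (medians -2.07 for interferon-stimulated and 1.25 for cell cycle genes). The 4OHT response differed with and without Cre in 6885 genes (medians 0.897 for interferon-stimulated and -2.34 for cell cycle genes).

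The rise of interferon-stimulated genes after Ku80 depletion was absent for most of the list in MAVS-knockout clones, which were other clones, in another set of libraries. A set of libraries unable to show such a rise is argued against, since the list rose by a median of 0.8971 (bootstrap interval over 71 genes 0.667 to 1.23) in the Cre difference, whose libraries belong to the same set. Genes already at the depleted level are argued against as the whole cause, since DMSO-treated MAVS-knockout clones stood above the 1-day DMSO clones of the same set by a median of 0.861 (0.435 to 1.17, 67 genes called at 4 days) against a 4-day change of 2.451, so a higher start stays open only as a part. Weaker or slower depletion in the MAVS-knockout clones stays open: 85 genes that changed early outside the interferon lists kept a median share of 0.621 of their 4-day change (0.599 to 0.662) against 0.0903 for the interferon-stimulated genes (0.0111 to 0.127), while in clones with MAVS these shares were 0.548 (0.483 to 0.584) and 0.147 (0.0652 to 0.228) at 1 day, 0.923 and 0.316 at 2 days, and 0.585 and 0.291 (0.239 to 0.363) at 2 days with the inhibitor. The first share at 1 day lies below that in MAVS-knockout clones. The same held for 67 genes picked without the 1-day libraries (0.483, 0.42 to 0.548, against 0.612, 0.597 to 0.666). This goes against so long a delay, but the second share overlaps and Ku80 protein was not analysed here. A weaker or delayed response and a MAVS-dependent one cannot be told apart. That MAVS carries the rise also remains a candidate explanation.

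With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real split gave the highest count in each comparison (1 of 10). The real count and the highest of the other splits were 3597 and 0 at 2 days of IAA, 6198 and 1 at 4 days, 6650 and 9 at 6 days, and 4644 and 21 for 6 against 2 days. They were 2119 and 0 for IAA with the inhibitor at 4 days, 1451 and 0 for the inhibitor alone, 886 and 0 for the inhibitor difference, 915 and 0 for the MAVS difference, 8702 and 0 for the MAVS baseline, and 3426 and 0 for Ku70 withdrawal. In MAVS-knockout clones they were 1488 and 95, and 0 among the 3 other splits that also part every pair of clones.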

How the results depend on the processing

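The fits without clone 13, with the 1-day control and with the Cre difference were chosen after seeing the data. Each of the 318 named values kept its direction and its side of the threshold with DESeq2 and with RLE factors. Among single libraries left out, 2050 values did so, 7 lost and 2 gained a call, and 1 turned: IFIT1 in MAVS-knockout clones, not called, went to 0.10 without the IAA library of clone 13 and to -0.59 without the DMSO library of clone 13. Limma on TPM values lost 4 named calls, the fit of only the compared groups lost 2 and gained 1, the block and the missing count filter gained 1 each (in all 3 cases IFIT1 at 2 days of IAA), and the fit without clone 13 lost 1. Causes not named below were not tested.

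Counts of calls moved by more than 1.5 times as follows. At 1 day, 35 became 127 without the filter, 159 with DESeq2, 15 with limma and 1607 with only the compared groups. With the inhibitor at 2 days, 78 became 250, 287, 28 and 575 in the same order. Only the compared groups in the fit, which leaves fewer libraries to estimate the spread, gave 3892 at 4 days, 2580 for 6 against 2 days, 438 for the inhibitor difference, 775 in MAVS-knockout clones, 341 for the MAVS difference and 1356 for 4OHT without Cre. DESeq2 gave 1350 for the inhibitor difference, 1398 for the MAVS difference and 1330 for 4OHT without Cre. Limma gave 1461 for the inhibitor difference, 612 for 4OHT without Cre and 2209 for Ku70 withdrawal. Without clone 13 in both arms, 756 genes were called in MAVS-knockout clones.

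The clone as a block, used because the same clones were in both arms, gave 107 calls at 1 day with 2 interferon-stimulated genes, 165 with the inhibitor at 2 days, 5404 for Ku70 withdrawal with 19 interferon-stimulated genes, and 5 such genes for the inhibitor difference. The block also ended 8 of the called list tests and RLE factors 2, and the block changed no other call of a list. In the Ku86flox/- cells the replicate numbers share only a number (correlations of 0.0246 and 0.0485 for 2 pairs), and as a block they gave 8960 calls after excision, 2238 without Cre and 6811 for the difference. With an estimated correlation the camera test of interferon-stimulated genes had an adjusted p of 0.234 at 1 day, 0.0811 at 2 days and 0.774 in MAVS-knockout clones, and 117 list tests in all were no longer called. The overlap of genes at least 2-fold up after Ku86 excision and Ku70 withdrawal did not pass on fewer genes (odds ratio 1.26). With the Cre difference it passed (1.92, Fisher's exact adjusted p = 0.0314). With the clone as a block Ku80 depletion and Ku70 withdrawal shared risen genes at an odds ratio of 1.13 (adjusted p = 0.0205).

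Leaving out single libraries gave these ranges for all genes and for interferon-stimulated genes: 3 to 8 and 0 to 0 at 1 day of IAA (where edgeR called 35 and 0 with all libraries), 2274 to 2999 and 24 to 33 at 2 days, 5052 to 6174 and 64 to 69 at 4 days, 5489 to 6710 and 67 to 68 at 6 days, and 3363 to 5264 and 59 to 62 for 6 against 2 days. With the inhibitor they were 4 to 9 and 1 to 2 at 2 days, 1260 to 1933 and 62 to 65 at 4 days, 767 to 1024 and 15 to 24 for the inhibitor alone, and 410 to 1466 and 3 to 5 for the difference. They were 892 to 1320 and 3 to 9 in MAVS-knockout clones, 529 to 1285 and 52 to 55 for the MAVS difference, and 7264 to 8049 and 26 to 31 for the baseline. They were 7371 to 7554 and 61 to 65 after excision, 773 to 2720 and 8 to 15 without Cre, 5679 to 7125 and 42 to 45 for the Cre difference, and 1164 to 4981 and 2 to 17 for Ku70 withdrawal. Depth limits the low genes, since 0 counts over a group bound a fold only from below: the floor was 0.0889 CPM in the 2-day DMSO controls, 0.0304 CPM after 6 days of IAA and 0.11 CPM in Cre-expressing cells with 4OHT.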

Other observations

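The tests of both patterns weighed here were chosen after the result was seen, and the genes of the first paragraph were chosen after their values were seen where the rule for named genes did not give them. Transcripts of interferons themselves were low. IFNB1 had 0 counts in the 2-day DMSO group and 2 counts after 6 days of IAA (0.0203 CPM), where edgeR did not test it. The lambda interferons IFNL1, IFNL2 and IFNL3 had 0 counts each in the 2-day DMSO group, 9, 12 and 11 after 4 days of IAA, and 24, 54 and 62 after 6 days, which put IFNL2 at least 6.16-fold higher at 6 days. IFNL1 stood at 0.243 CPM after 6 days (exact Poisson interval 0.156 to 0.362), and IFNL2 and IFNL3 are near-identical copies whose counts are uncertain. In MAVS-knockout clones these 3 genes had 0, 0 and 0 counts with DMSO and 0, 0 and 1 with IAA. In Cre-expressing Ku86flox/- cells they had 4, 3 and 1 counts with ethanol and 12, 8 and 17 with 4OHT, and without Cre 0, 0 and 0 with ethanol and 0, 0 and 2 with 4OHT. IFNE went from 6 counts (0.178 CPM) in the 2-day DMSO group to 49, 77 and 117 counts (1.25, 1.49 and 1.19 CPM) after 2, 4 and 6 days of IAA. In MAVS-knockout clones it had 20 counts (0.484 CPM) with DMSO and 53 (1.18 CPM) with IAA. The chemokine CXCL10 had 0 counts in the 2-day DMSO group and 32 after 6 days of IAA, and CCL5 went from 18 counts (0.531 CPM) to 64 (2.35 CPM) after excision, and from 3 counts (0.099 CPM) to 10 (0.318 CPM) with 4OHT without Cre. In HEK293 IFNB1 had 0 counts with and 5 without doxycycline (0.0757 CPM), and CXCL10 4 and 25 (0.052 and 0.378 CPM).

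Some genes were called in the same direction at 4 days of IAA, after Ku70 withdrawal and in the Cre difference. Of 12584 tested in all 3, they numbered 179 up (75.6 for independent lists) and 234 down (80.4). This comparison was chosen after seeing the data. A positive Cre difference is not always a rise after excision, since a fall with 4OHT without Cre also gives one. PPP1R15A (1.12) and KLF6 (0.528) counted as up, yet 4OHT without Cre lowered both by more than that difference. EIF3B fell early in the degron clones and fell in the other cells too. Its log2 change was -2.77 at 4 days of IAA, -1.57 in MAVS-knockout clones, -0.96 after Ku86 excision and -0.97 after Ku70 withdrawal, against -0.09 for 4OHT without Cre (edgeR adjusted p = 0.229).

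The early fall of EIF3B, MRPS35 and CAD, like other changes after IAA, could come from doxycycline or IAA and not Ku80 loss. Only the depleted arm received them. EIF3B also fell in the 4-day Cre difference, where neither compound was used (-0.8637, 95% interval -1.06 to -0.667 on 4 residual degrees of freedom). No Cre libraries were read at 1 day, so the compounds stay open for the early fall. For MRPS35 the interval of the same test leaves the compounds open (-0.1082, -0.392 to 0.176). CAD fell there as well (-0.3289, -0.53 to -0.128, edgeR adjusted p = 0.00256) and after excision (-0.57), but the interval does not lie below the cut of -0.3 set for this test, and 4OHT without Cre also lowered CAD (-0.24), so the compounds as a part of its larger fall in the degron clones stay open. A link of EIF3B to Ku stays a hypothesis, as no Ku-intact cells received both compounds or active Cre.

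Interferon-stimulated genes did not rise as a list after Ku70 withdrawal in HEK293. The median upper 95% limit of their change was 0.5272 (bootstrap interval 0.383 to 0.827, 65 genes), below their median 0.8777 in the Cre difference. The bootstraps here and above resample genes, not clones, so clone-level imprecision stays open. Low expression alone is argued against, because the 49 members with an average log2 CPM of at least 1 had a median change of -0.2283 (-0.411 to 0.0748). The cell line, the ribosome-depleted libraries, the remaining 454.3 CPM of XRCC6, the 8-day time point and doxycycline, here given to the arm with Ku, differ together from the HCT116 experiments. Which of them matters was not tested.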
